A study of Homo sapiens with 16 samples.

How the data were processed

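Nascent RNA was measured in HEK293T cells, an embryonic kidney line that carries the SV40 large T antigen, either wild type or labelled METTL3 knockout. Per the labels' protocols, 5-ethynyluridine (EU), a uridine analogue that RNA polymerases build into new transcripts, was added to 0.5 mM. Cells were harvested 10, 20, 30 or 60 min later, labelled RNA was captured by click chemistry on beads, and stranded total RNA libraries were made on the beads. The 16 libraries formed 8 groups of 2, a group being a genotype at a labelling time, and the libraries were assigned from their titles. The labels do not say whether the 2 replicates of a group came from separate cultures, how the knockout was made or whether it is a clone.

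The authors deposited 4 tables of whole-number fragment counts. Alignment with HISAT2 2.2.1 to hg38 and counting with featureCounts are named in the submitters' processing notes. Per the file headers, featureCounts 2.0.1 counted fragments in reverse-stranded mode over the exons of GENCODE 43 genes, over HOMER's intergenic regions and over the 92 ERCC spike-in transcripts. The intron table gives no command, so its counter settings are not given in the sources used here. Its 329001 deposited rows are introns of RefSeq transcripts, and 99.6% belong to genes on the plus strand. Of these rows, 88.4% overlap another row, and 2.0% of the overlapping rows hold any counts, against 83.5% of the 38152 that do not overlap. All 20293 intergenic regions are listed on the plus strand, so with stranded counting only plus-strand RNA was counted there. Genes of the gene table lie inside some of these regions, so they are not all outside genes. The intron and intergenic tables therefore describe part of the unspliced and intergenic RNA. METTL3 has 0 intron rows. When the spike-ins were added, and per what amount of RNA or cells, is not given in the labels. No molecular identifiers are given for these counts, so PCR copies count as separate fragments, and intervals and floors below cover counting error only.

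Gene symbols were found for 62686 of 62703 gene identifiers in a gene name table. Intron counts were summed per gene symbol, and 99.5% of intron counts fell in rows matched to a symbol. Mitochondrially encoded genes hold 0 counts in the gene table and could not be tested. Gene totals ran from 3221166 to 9799764 counts per library, intron totals from 2067542 to 7024840, and spike-in totals from 2385671 to 21254034.

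Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter by group (minimum count 10, minimum total 15) and quasi-likelihood F tests on group means. All 16 libraries entered each fit, so that the 8 groups of 2 shared an estimate of the spread. Contrasts were knockout minus wild type averaged over the 4 times, the same at each time, an F test of equal genotype differences over the 4 times, and 60 minus 10 min averaged over genotypes. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Standard errors (SE) were the absolute log2 fold change divided by the square root of F. Levels are CPM (library-size scaled counts) on TMM-adjusted library sizes, as mean ± SD over the 8 libraries of a genotype, so this SD includes the labelling times. The intron to exon ratio was log2((intron count + 2)/(exon count + 2)) per gene, centred per library, and was tested with limma 3.58.1. Gene lists were tested with limma's camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 31 lists. Of 32 lists fixed beforehand, the mitochondrially encoded genes had no testable member. Measures per library were compared by exact two-sided permutation of genotype within each time (1296 arrangements), or of time over 8 libraries (70 arrangements). The length measure was the median log2 CPM of the longest 20% of genes by genomic span, from 76884 bp, minus that of the shortest 20%, up to 1746 bp. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and plots.

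Named genes followed a rule set before the data were examined, as were the gene lists, the tests and most alternatives. The rule took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and the same direction at all 4 times, which 2729 genes met. It added METTL3, METTL14, WTAP and the histone acetyltransferase list, and up to 4 members of each list with the smallest p. For labelling time it took the 6 largest each way, for the interaction the 5 smallest p, for introns the 5 largest each way, and for intergenic regions and the intron to exon ratio the 4 largest each way. Genes used only to infer sex were left out, and some genes that the rule names are not reported here. A ratio against a genotype with 0 counts was set against a floor of 3 counts over that genotype, and written as a lower bound. With 1 to 3 counts the pooled ratio is given with a 95% exact interval.

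Each test was checked on simulated counts drawn with each gene's mean over all libraries, the real library sizes and 1 spread per gene shared by all groups. Genes were drawn independently of each other. Real replicates scattered 7.39 to 32.8 times beyond counting noise, depending on the group, which these counts do not copy. The shares and false calls below therefore hold for the simulated counts and may differ in the real data. For the average genotype effect, over 20936 simulated genes, 17.9% of genes changed 1.5-fold were recovered, 29.9% of those changed 2-fold and 51.5% of those changed 4-fold, with 7 of 73 calls false. At 10 min, over 20935 genes, the shares were 0%, 2.99% and 22.7%, with 0 of 17 calls false. For labelling time, over 21013 genes, they were 5.97%, 17.9% and 45.5%, with 2 of 48 false. For the interaction, over 20935 genes, they were 0%, 1.49% and 18.2%, with 1 of 14 false. For introns, over 6594 genes, they were 19.4%, 34.3% and 37.9%, with 3 of 64 false, and for intergenic regions, over 9903, they were 2.99%, 13.4% and 28.8%, with 2 of 32 false. For the intron to exon ratio, over 5130 genes, they were 0%, 0% and 13.6%, with 1 of 10 false. Among 31 lists, a list raised 2-fold was the 1 list called.

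Alternatives were DESeq2-style size factors, scaling by the ERCC totals, DESeq2 1.42.0, no filter, the replicate number as a block, an additive model, a test against a 1.2-fold change, fits of subsets of libraries, other pseudocounts, length measures and gene sets, camera with an estimated correlation, fry, and each library left out in turn. Alternatives chosen after seeing the data left out the 10 min or the 20 min libraries, summed or averaged replicates, or kept genes found in both tables. Intergenic neighbours were taken from the coordinates of the gene table.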

Results

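The series measured newly made RNA in HEK293T cells that were wild type or labelled METTL3 knockout, after 10, 20, 30 and 60 min of EU labelling, with 2 libraries in each of the 8 groups. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The series title links it to histone acetyltransferase HAT1 and to acetylation of histone H3 at lysine 9. Gene counts per library ran from 3221166 to 5482055 at 10 min, 7006721 to 9799764 at 20 min, 4197016 to 6084238 at 30 min and 6040471 to 6985571 at 60 min. The ERCC spike-ins took 67.6% to 71.0% of all counts at 10 min, 35.9% to 43.8% at 20 min, 31.1% to 47.7% at 30 min and 17.7% to 20.4% at 60 min. Between 13904 and 18066 genes had at least 10 counts in a library. The replicates of each group differed by more than counting noise, with a mean chi-square ratio from 7.39 in wild type at 60 min to 32.8 in knockout at 10 min, so no libraries were merged as copies. The labels do not state that replicates were separate cultures, and the p-values then measure only the spread between these libraries, which may be technical.

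METTL3 itself was read at similar or higher levels in the libraries labelled knockout. Its exon counts gave 64.6 and 70.9 CPM in the wild-type libraries at 10 min, 63.6 and 70.6 at 20 min, 76.97 and 78.2 at 30 min, and 119 and 130 at 60 min. In the libraries labelled knockout they gave 96.0 and 146 CPM at 10 min, 77.9 and 102 at 20 min, 76.5 and 101 at 30 min, and 140 and 156 at 60 min. The average log2 fold change was 0.43 ± 0.13 (SE, n = 8 libraries per genotype, adjusted p = 0.0143). A knockout by a small lesion leaves transcription of the gene in place, and the labels do not give the lesion, so these counts over the whole gene (hg38, chromosome 14, 21498133 to 21511342) do not check the genotype labels. The METTL3 call was lost in 6 of 25 alternatives: without the second knockout library at 30 min, the first wild-type library at 60 min or the first knockout library at 20 min, without the 10 min libraries, with replicates summed (the last pair chosen after seeing the data) and against a 1.2-fold change, with values from 0.29 to 0.75 over all 25. Directions below are those of the groups as labelled.

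Around METTL3, 4 of the 8 tested genes of the m6A writer complex were lower in the libraries labelled knockout and METTL3 was higher (4 lower and 3 higher when adjusted over the list alone; camera adjusted p = 0.643). WTAP, the subunit that places the complex in nuclear speckles, fell by 0.37 on the log2 scale (SE 0.09, adjusted p = 0.00121), from 282 ± 29.02 to 220 ± 38.2 CPM (SD, n = 8). CBLL1 had a log2 fold change of -0.47, RBM15 of -0.36 and ZC3H13 of -0.29, all past the threshold. RBM15 stood at -0.82 at 10 min and from -0.29 to -0.15 at the later times, and its call was lost without the 10 min libraries. The WTAP, RBM15 and ZC3H13 calls were lost with replicates summed (both alternatives chosen after seeing the data), and these and the CBLL1 call against a 1.2-fold change. METTL14, the partner of METTL3, did not pass, at -0.16 ± 0.12 (SE, adjusted p = 0.447). Of the readers and erasers of m6A, 2 of 14 rose and 3 fell (2 and 5 adjusted over the list alone): the demethylase gene ALKBH5 (0.59 ± 0.20) and YTHDF3 (0.30 ± 0.11) rose, and the readers IGF2BP1 (-0.45 ± 0.08), IGF2BP2 (-0.38 ± 0.11) and YTHDF1 (-0.63 ± 0.20) fell. METTL1 and WDR4, which together methylate guanosine in transfer RNA, both rose, by log2 fold changes of 1.12 ± 0.20 and 0.81 ± 0.11, and were the 2 of 11 other RNA methyltransferase genes that changed (2 and 0 adjusted over the list alone). These sizes are relative to the other genes. Scaling by ERCC counts moved the median of all genes to 0.30, the ZC3H13 value turned to 0.03, and WTAP (-0.06), RBM15 (-0.05) and CBLL1 (-0.15) were no longer past the threshold. By that scaling 3 writer genes were higher and 0 lower, 8 readers and erasers higher and 0 lower, and 5 other methyltransferase genes higher and 0 lower. The ALKBH5 call was lost in 10 of 25 alternatives (values from 0.41 to 0.91), 7 of them leaving out 1 library, the YTHDF1 call in 7 (-0.79 to -0.33) and the IGF2BP2 call in 5 (-0.42 to -0.06).

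HAT1 did not differ detectably, at 121 ± 29.2 CPM in wild type and 115 ± 35.3 in knockout (SD, n = 8; log2 fold change -0.09 ± 0.13 SE, adjusted p = 0.749), and its sign turned with ERCC scaling (0.22). Among the 23 histone acetyltransferase genes and partners, 5 fell and 2 rose (8 and 2 adjusted over the list alone). KAT7, the catalytic subunit of HBO1 complexes, fell from 284 ± 61.0 to 164 ± 42.1 CPM (log2 fold change -0.79 ± 0.10, adjusted p = 8.05e-09). NCOA1 (-0.60 ± 0.13), RBBP4 (-0.33 ± 0.08), GTF3C4 (-0.32 ± 0.11) and BRPF1 (-0.40 ± 0.14) also fell, while KAT14 (1.15 ± 0.25) and ELP3 (0.64 ± 0.20) rose. EP300 (0.10 ± 0.07), CREBBP (-0.04 ± 0.08), KAT2A (0.02 ± 0.24), KAT2B (-0.87 ± 0.36), KAT5 (0.58 ± 0.26), KAT6A (0.08 ± 0.07), KAT6B (0.06 ± 0.08), KAT8 (0.23 ± 0.22), NCOA3 (-0.14 ± 0.14), TRRAP (-0.19 ± 0.07), TADA2A (-0.14 ± 0.16), TADA3 (-0.27 ± 0.32), TAF1 (-0.05 ± 0.09), RBBP7 (-0.20 ± 0.07) and BRPF3 (-0.08 ± 0.17) did not pass. The list as a whole was not called (camera adjusted p = 0.498). The BRPF1 call held in 11 of 25 alternatives (values from -0.49 to -0.09) and the GTF3C4 call in 9 of 25 (-0.36 to -0.002), each lost on leaving out any of several single libraries. The ELP3 call was lost in 4 of 25 (0.44 to 0.96), among them those without the first wild-type library at 60 min, the second knockout library at 10 min or the first at 20 min. With ERCC scaling 8 genes of the list were higher and 1 lower: GTF3C4, BRPF1, RBBP4 and NCOA1 were not called, and CREBBP turned to 0.28 and TAF1 to 0.27 (adjusted p = 0.0268) and both were called.

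Averaged over the labelling times, 4041 of 22337 tested genes differed between the genotypes, 1960 higher and 2081 lower in the libraries labelled knockout, and 1871 of them by over 2-fold. The strongest differences were close to all or none. FLRT2, a membrane adhesion protein, went from 0.214 ± 0.281 CPM in wild type to 39.8 ± 14.9 in knockout (SD, n = 8; log2 fold change 8.70 ± 0.57 SE, adjusted p = 6.68e-17). ARHGAP6 had 0 counts in all 8 wild-type libraries and 433 in knockout, at least 132-fold higher by counting error alone. Replicates scattered 7.39 to 32.8 times beyond counting noise. This bound, and the bounds and intervals of count ratios below, are therefore tighter than the data allow. Other rises of this size were in the zinc finger genes ZNF682 (7.92 ± 0.73) and ZNF347 (7.11 ± 0.96), the protease gene ADAMTS12 (7.81 ± 0.66), FBXL7 (7.45 ± 0.99), HIF3A (6.99 ± 1.05), LINC02519 (6.75 ± 0.84) and RANP4 (7.20 ± 0.90). RANP4 is a processed pseudogene, so its reads may belong to related copies.

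In the other direction, NEFM, the medium neurofilament subunit, fell from 90.7 ± 37.4 to 0.0792 ± 0.131 CPM (SD, n = 8; log2 fold change -10.03 ± 0.40 SE, adjusted p = 2.25e-25), and LCP1, the actin-bundling protein L-plastin, from 64.3 ± 11.2 to 0.143 ± 0.335 CPM (-9.86 ± 0.50, adjusted p = 6.96e-21). OXCT1, a mitochondrial enzyme of ketone body use, had 1623 counts in wild type and 1 in knockout, a pooled ratio of 1779 with a 95% interval from 319 to 70319. The ratio was 1029 for MNS1 (939 against 1 count, interval 184 to 40702), 831 for DECR1 (758 against 1, interval 149 to 32864), 713 for the potassium channel gene KCNT2 (1301 against 2, interval 197 to 5895) and 386 for MAGEA6 (705 against 2, interval 107 to 3197). ZFP82 and POTEF had 0 counts in knockout and were at least 191-fold and 188-fold lower by counting error alone. SORBS2 fell from 20.7 ± 8.77 to 0.119 ± 0.337 CPM. POTEF and MAGEA6 have near-identical relatives, and their counts are uncertain for that reason. Scaled by ERCC counts, the split of calls moved from 1960 higher and 2081 lower to 4287 higher and 965 lower. The number past the threshold was 2653 when tested against a 1.2-fold change, and 2255 when replicates were summed, an alternative chosen after seeing the data.

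Genes of the HOX clusters, which set position along the body axis, rose together. Of 35 tested, 22 rose and 0 fell (23 rose when adjusted over the list alone), with a median log2 fold change of 0.80 and camera adjusted p = 8.93e-12, or adjusted p = 0.00434 with an estimated correlation. The rise covered 10 of 11 HOXA, 6 of 9 HOXB and 6 of 8 HOXC genes, and 0 of 7 HOXD genes passed the test. HOXC9 went up by 1.84 ± 0.12, HOXC8 by 1.99 ± 0.17, HOXB6 by 1.43 ± 0.08 and HOXA3 by 1.38 ± 0.09 (log2, SE). HOXB8 rose by 1.49 ± 0.16 and HOXA2 by 1.74 ± 0.18, while HOXD10 stood at 0.22 ± 0.11. Scaled by ERCC counts, the list median was 1.11 and 25 members rose, including 1 of the 7 HOXD genes (cluster median 0.47, against 0.15). Members of a cluster lie side by side and overlap in places (hg38, HOXA3 at chromosome 7, 27106184 to 27152583, spans HOXA4, HOXA5 and HOXA6), so their counts are not fully separate.

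**Figure D1:**
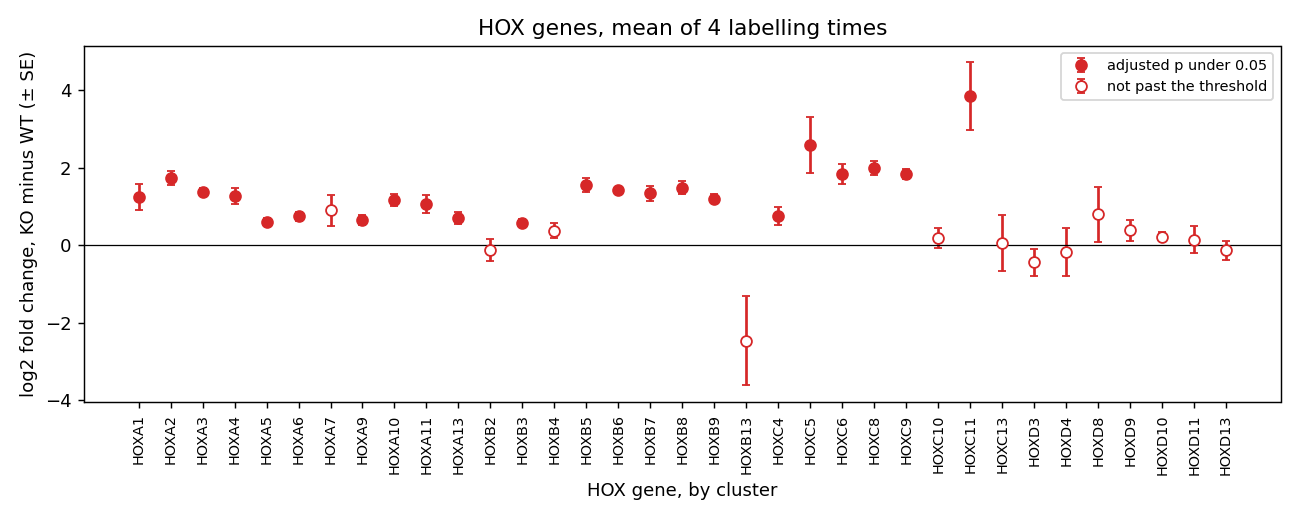
The y axis is the log2 fold change of each HOX gene, knockout minus wild type averaged over the 4 labelling times, and the x axis lists the 35 tested genes by cluster. Points are edgeR estimates with bars of 1 SE, filled where the adjusted p is under 0.05: 22 genes of HOXA, HOXB and HOXC lie above 0 and pass, and 0 of the 7 HOXD genes pass (1 with ERCC scaling).

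Zinc finger genes named ZNF, many of which encode KRAB repressors, also rose: 121 of 455 rose and 17 fell (137 and 20 when adjusted over the list alone; median 0.42, camera adjusted p = 3.36e-07, adjusted p = 0.000164 with an estimated correlation). ZNF813 rose by 6.68 on the log2 scale, ZNF91 by 3.85, ZNF577 by 1.94 and ZNF331 by 1.88, and ZNF483 (-1.30 ± 0.17) and ZNF664 (-0.83 ± 0.12) were among those that fell. Scaled by ERCC counts, 229 ZNF genes were higher and 10 lower, with a median of 0.74. Immediate early genes, which respond first to growth factors and stress, rose in 13 of 41 cases and fell in 1 (13 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 0.00447, adjusted p = 0.0306 with an estimated correlation). ZFP36L1 (1.18 ± 0.14), CCN1 (1.37 ± 0.20), ZFP36L2 (0.99 ± 0.15) and JUN (0.56 ± 0.08) had the smallest p among them, and others rose by more, such as FOS (2.05 ± 0.60). DUSP2, with 168 counts in wild type and 1 in knockout, was the member that fell. ERCC scaling gave 19 higher and 1 lower, with a median of 0.70.

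Integrated stress response genes went the other way, with 13 of 31 lower and 1 higher (the same counts adjusted over the list alone; median -0.45, camera adjusted p = 0.00015, adjusted p = 0.0117 with an estimated correlation). These are mostly genes of amino acid supply under the factor ATF4. SLC7A11, the cystine transporter, fell from 126 ± 21.3 to 19.6 ± 8.83 CPM (SD, n = 8; log2 fold change -2.73 ± 0.18 SE), STC2 by -1.78 ± 0.15, CTH, which makes cysteine, by -1.62 ± 0.23, and PHGDH, the entry enzyme of serine synthesis, by -1.23 ± 0.11. ASNS fell by 0.98 on the log2 scale, and CBS was the member that rose (0.96 ± 0.19). With ERCC scaling the median was -0.13, with 8 members lower and 7 higher.

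Replication-dependent histone genes and p53 targets were called higher by camera with the preset correlation but not with an estimated one. Of 50 histone genes, 6 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 0.000327, but adjusted p = 0.248 with an estimated correlation): H2AC6 (2.60 ± 0.20), H2AC8 (4.19 ± 0.73), H2BC8 (4.98 ± 1.48), H2BC12 (1.04 ± 0.29), H2AC20 (1.36 ± 0.48) and the linker histone gene H1-2 (0.39 ± 0.14). Histone genes are near-identical copies, and their counts are uncertain for that reason. The mean level of H2BC8 went from 0.485 ± 1.37 to 2.58 ± 2.05 CPM (SD, n = 8), much less than its fitted 31.5-fold. H2BC8 stood at -1.10 at 10 min, and its call was lost in 3 of 25 alternatives (values from 3.65 to 7.15), among them that without the first knockout library at 10 min. The H2BC12 call was lost without the first wild-type library at 60 min (range 0.79 to 1.36). Of 25 p53 target genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 0.0142, but adjusted p = 0.214 with an estimated correlation), among them TP53I3 (4.47 ± 0.65), PHLDA3 (3.66 ± 0.82) and the death receptor gene FAS (1.99 ± 0.38), while the phosphatase gene PPM1D fell (-0.63 ± 0.12). PHLDA3 stood at 7.99 at 10 min and 1.41, 1.57 and 3.68 at the later times, and its call was lost without the 10 min libraries (values from 2.22 to 5.40 over 25 alternatives). Scaled by ERCC counts, 12 p53 targets were higher and 0 lower, and 9 histone genes were higher and 0 lower. The p53 call was lost in 4 of 20 alternatives, the others being those without the first knockout library at 10 min (5 lists called), without all 10 min libraries and with replicates summed, the last pair chosen after seeing the data.

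The remaining lists were not called by camera. Counts in brackets below are those adjusted over the list alone, higher first, and the balance of many lists turned with ERCC scaling. Of 21 histone deacetylase genes, 4 rose, NCOR1 (0.47 ± 0.07) among them, and 3 fell (5 and 3), SIN3A (-0.73 ± 0.09), SIRT1 (-0.65 ± 0.11) and HDAC2 (-0.58 ± 0.08). Of 25 genes of H3K9 methylation and heterochromatin, 4 rose, including MORC2 (0.69 ± 0.13), ATF7IP (0.51 ± 0.08) and KDM1A (0.44 ± 0.08), and 4 fell (4 and 5), including the demethylase gene KDM4C (-0.75 ± 0.14). RNA polymerase II and elongation factors had 5 of 41 higher and 5 lower (5 and 7), and the 2 subunits of the FACT complex parted, SSRP1 at -0.91 ± 0.11 and SUPT16H at 0.63 ± 0.08. Of 37 G2 and M phase genes 3 rose and 8 fell (3 and 8), and of 35 G1 and S phase genes 3 rose and 9 fell (4 and 12), with BRIP1 (-0.67 ± 0.08), GMNN (-0.64 ± 0.10) and CDC45 (-0.62 ± 0.12) lower and MCM4 (0.45 ± 0.07) higher. Ribosomal protein genes had 13 of 83 higher, RPS2 (0.62 ± 0.07) among them, and 21 lower (15 and 22), such as RPL21 (-0.76 ± 0.09) and RPL5 (-0.56 ± 0.06). Of 35 ribosome biogenesis genes 6 rose and 3 fell (7 and 4). Nuclear genes of oxidative phosphorylation had 7 of 76 higher and 5 lower (7 and 5), and the largest, UQCRHL (4.79 ± 0.33), is a near copy of another gene and is uncertain. ERCC scaling gave 13 higher and 0 lower for G2 and M phase, 9 and 3 for G1 and S phase, 41 and 5 for ribosomal proteins, 18 and 0 for ribosome biogenesis and 18 and 1 for oxidative phosphorylation. It gave 6 and 3 for deacetylases, 6 and 1 for heterochromatin and 12 and 1 for RNA polymerase II and elongation factors.

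Among stress and metabolic lists, unfolded protein response genes had 3 of 20 higher and 7 lower (3 and 7 adjusted over the list alone, as in the brackets below), with DNAJC3 (-1.02 ± 0.17), XBP1 (-0.93 ± 0.20) and CANX (-0.65 ± 0.07) lower. Heat shock genes had 3 of 19 higher and 6 lower (3 and 8). Cholesterol synthesis genes had 1 of 24 higher and 2 lower (1 and 2), SC5D at -1.36 ± 0.15, and glycolysis and hypoxia genes 4 of 31 higher and 7 lower (4 and 7), with ADM at -5.27 ± 0.68 and PKM at -0.64 ± 0.09. Interferon-stimulated genes had 0 of 29 higher and 4 lower (0 and 3), although the list median was 0.21 and the camera direction higher. PARP9 had 207 counts against 3, a ratio of 75.6 (95% interval 25.5 to 370), DTX3L 174 against 2, a ratio of 95.4 (interval 26.01 to 794), and OAS3 45 against 0. The OAS3 call was kept in 3 of 23 alternatives and was lost whichever of the 16 libraries was left out, and the DTX3L call was lost without the second wild-type library at 10 or at 30 min. Among noncoding RNAs, MALAT1 rose (0.49 ± 0.03) and NEAT1 fell (-0.98 ± 0.09), within 4 of 25 nuclear and host long noncoding RNAs higher and 4 lower (5 and 4). Small nuclear RNA genes had 4 of 308 higher and 10 lower (0 and 0), and small nucleolar RNA genes 3 of 149 higher and 3 lower (0 and 1). Of 7 RNA polymerase III transcripts RN7SL1 was higher and RMRP and VTRNA1-3 lower (1 and 3). The VTRNA1-3 call was kept in 8 of 25 alternatives (values from -1.94 to -1.24), and the RMRP call was lost in 5 of 25 (-1.24 to -0.65), among them those without the second wild-type library at 20 min or the first knockout library at 30 min. Many of these small RNA genes are pseudogene copies, and their counts are uncertain. ERCC scaling gave 3 higher and 3 lower for the unfolded protein response, 5 and 1 for heat shock, 4 and 2 for cholesterol synthesis, 7 and 3 for glycolysis and hypoxia and 3 and 3 for interferon-stimulated genes. For RNA classes it gave 14 and 2 (long noncoding), 12 and 7 (small nuclear), 8 and 2 (small nucleolar) and 1 and 0 (RNA polymerase III).

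Markers of other cell types also differed, with counts adjusted over the list alone in brackets. Extracellular matrix and mesenchymal genes had 6 of 30 higher, VIM (0.99 ± 0.12) among them, and 6 lower (7 and 6), with COL5A2 at -7.15 ± 0.72 and ZEB2 at -1.15 ± 0.11. Neuronal genes had 2 of 18 higher, KIF5A (1.52 ± 0.19) and NEFL (0.82 ± 0.28), and 4 lower (3 and 5), NEFM, UCHL1 (-6.52 ± 0.43), NRXN3 and ELAVL2. Blood cell markers had 0 of 7 higher and 1 lower (0 and 1), LCP1, and epithelial and hepatic markers had 0 of 5 higher and 3 lower (0 and 3), KRT8, KRT18 and CDH1. The KRT18 call was kept in 11 of 25 alternatives, with values from -4.37 to -0.72, and was lost on leaving out any of 8 single libraries. The KRT8 call was lost in 4 of 25, among them that without the second knockout library at 60 min, and the CDH1 call without the first wild-type library at 30 min. ERCC scaling gave 9 higher and 3 lower for extracellular matrix, 3 and 3 for neuronal, 0 and 1 for blood and 0 and 1 for epithelial and hepatic genes. For the blood, neuronal and extracellular matrix lists the medians (0.75, 0.21 and 0.09) and the camera direction (lower) had opposite signs. The reader and heat shock lists had medians of 0.05 and -0.12 and means of -0.03 and 0.05.

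The genotype difference was also tested at each labelling time, with 2 libraries against 2. At 10 min 936 genes were higher in the libraries labelled knockout and 1128 lower, at 20 min 330 and 419, at 30 min 399 and 279, and at 60 min 217 and 290. FLRT2 was higher at each time (log2 fold changes 10.73, 6.11, 10.21 and 7.73). With ERCC scaling the splits moved with the spike-in ratio, to 1583 higher and 684 lower at 10 min, 184 and 1184 at 20 min, 5575 and 84 at 30 min, and 626 and 112 at 60 min. Leaving out 1 library gave from 412 (first wild-type library at 20 min) to 1343 genes (second knockout library at 10 min) at 20 min, 386 (first knockout library at 30 min) to 1206 (first at 10 min) at 30 min and 226 (first knockout library at 60 min) to 872 (second at 10 min) at 60 min. DESeq2 called 4131, 1525, 1497 and 948 genes at the 4 times, and fits of a time alone 81 at 10 min and 2628 at 60 min, so the number of calls per time does not rank the times. Replicate scatter over counting noise was 26.8 (wild type) and 32.8 (knockout) at 10 min, and 7.39 and 9.17 at 60 min. The fit of all libraries used 1 spread per gene for every group. That spread may be too small at 10 min, where calls may be overstated, and too large at 60 min.

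Whether the genotype difference changed with labelling time was tested directly, and 39 genes passed. NTHL1, a DNA repair glycosylase, was lower in the libraries labelled knockout at 30 min (log2 fold change -1.40 ± 0.22 SE, n = 2 per group) and higher at 20 min (1.25 ± 0.23) and 60 min (1.35 ± 0.22), with 0.44 ± 0.22 at 10 min (adjusted p = 1.45e-07). ADAMTS1 ran -0.25, -0.44, -1.23 and 0.38 over the 4 times, the splicing factor gene SRRM2 0.34, -0.46, 0.40 and -0.11, and MALAT1 0.41, 0.25, 0.87 and 0.42. MTATP6P1 (1.09, -0.24, 0.48 and -0.18) is a nuclear copy of a mitochondrial gene and is uncertain. At an unadjusted p under 0.05 there were 1936 genes. The count was 809 with DESeq2, 4109 with ERCC scaling, 93 with no filter and 90 with the replicate block. The count rose whichever of the 16 libraries was left out, to between 69 (second knockout library at 30 min) and 539 (second knockout library at 10 min).

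From 10 to 60 min of labelling, 1758 genes changed in their share of the labelled RNA, 1057 higher and 701 lower at 60 min. MAP4K3-DT and CBR3-AS1 had 0 counts in the 4 libraries at 10 min and were at least 47.3-fold and 50.2-fold higher at 60 min by counting error alone. ZNF83 had 2 counts at 10 min and 233 at 60 min, a ratio of 72.8 (95% interval 19.9 to 605), and RNU6-714P 1 and 137, a ratio of 85.6 (interval 15.1 to 3407). The histone gene H2BC17 (6.71 ± 1.26) and EFCAB6 (6.41 ± 1.29) also rose. The 6 named rises had 0 to 6 counts in the 10 min libraries, where fewest genes were detected (13904 to 15004 with at least 10 counts). Low detection at 10 min and labelling time cannot be told apart for these rises. PSG4, a pregnancy-specific glycoprotein gene, fell from 42.5 ± 20.4 to 3.88 ± 1.83 CPM (SD, n = 4; log2 fold change -3.34 ± 0.42 SE, adjusted p = 8.36e-08), and the keratin gene KRT8 (-3.83 ± 1.14), B3GALT4 (-3.59 ± 1.00), RNU6-890P (-4.78 ± 1.45), RN7SL448P (-3.76 ± 1.14) and RNU4-1 (-2.95 ± 0.68) fell. Leaving out 1 library ended the call in 6 cases for RNU6-890P (values up to -0.41), 5 for KRT8 (up to -1.38), 5 for RN7SL448P (up to -3.12) and 3 for B3GALT4 (up to -3.09), the first 3 highest without the first knockout library at 10 min. Pooled counts gave smaller changes than the fit for H2BC17 (35.6-fold against 105-fold) and EFCAB6 (30.6-fold against 85.2-fold). They also did for RNU6-890P (3.82-fold against 27.5-fold) and KRT8 (6.25-fold against 14.2-fold), and were close to the fit for PSG4 (10.6-fold against 10.1-fold). PSG4, H2BC17, RNU6-714P, RNU6-890P, RN7SL448P and RNU4-1 have near-identical copies and are uncertain. These are shares of labelled RNA: with ERCC scaling all 18058 calls were higher at 60 min and RNU4-1 turned to 0.36, and with DESeq2-style size factors the split was 862 and 862. DESeq2 called 3162 genes, and fits of wild type and knockout alone 437 and 511. The count was 1082, 1110 and 1142 without the second or first wild-type library or the second knockout library at 60 min.

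Intron reads, which come from RNA not yet spliced, showed 1646 of 6957 genes changed between genotypes, 844 higher and 802 lower in the libraries labelled knockout. LINC01036 introns fell from 1631 ± 332 to 7.69 ± 3.27 CPM (SD, n = 8; log2 fold change -7.74 ± 0.13 SE, adjusted p = 7.52e-33), and its exons fell too (-8.69). LINC02315 (-7.90 ± 0.26), LINC01037 (-8.62 ± 0.45), SMIM3 (-7.88 ± 0.74) and the GTPase gene RAB32 fell, RAB32 with 1309 counts in wild type and 3 in knockout, a ratio of 450 (95% interval 154 to 2187). MISP (7.72 ± 1.04), DLGAP1-AS4 (6.51 ± 0.63), DLGAP1-AS5 (6.40 ± 0.65), ZNF385D-AS1 (6.35 ± 0.84) and TRIB2 (6.33 ± 1.07) rose. Pooled counts gave smaller rises than these fitted sizes: 48.8-fold, 36.2-fold, 54.5-fold, 46.4-fold and 15.1-fold in that order. They also gave smaller falls for LINC01037 (169-fold) and SMIM3 (122-fold). Of 5413 genes tested in both tables, 600 changed in both, 590 of them in the same direction, and the log2 fold changes had a Pearson r of 0.52 across genes, which are not independent replicates. With ERCC scaling the split was 1404 higher and 484 lower, and 1096 genes passed with replicates summed, chosen after seeing the data.

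The ratio of intron to exon reads per gene, a measure of how much of a gene's RNA was unspliced, changed for 31 of 5413 genes, 15 higher and 16 lower. ZNF544 (5.27 ± 0.42 SE, adjusted p = 0.000692), SEMA6D (4.12 ± 0.47) and ADAMTS19 (2.80 ± 0.35) had a higher ratio in the libraries labelled knockout. GABRQ (-4.82 ± 0.70) and LINC00534 (-4.08 ± 0.35) had a lower one. ZNF544 had 4 exon counts over the 8 knockout libraries, and GABRQ 11 and LINC00534 20 over the 8 of wild type, so the pseudocount of 2 affects these sizes. Exon and intron log2 fold changes had opposite signs for SEMA6D (-1.01 and 3.05) and ZNF544 (-7.28 and 0.78). They also did for GABRQ (4.92 and -3.12) and LINC00534 (5.43 and -2.01), while both fell for ADAMTS19 (-4.07 and -0.66). These ratios alone therefore do not show a change in splicing. NEFM, LINC02315 and SMIM3 also passed, but the 8 knockout libraries held 4, 0 and 0 exon counts and 0, 48 and 8 intron counts, so the pseudocount largely sets their values and no change of the ratio is read from them. The LINC02315 and SMIM3 calls were lost with a pseudocount of 0.5, and those of SEMA6D, ADAMTS19, GABRQ and LINC02315 without the 10 min libraries, chosen after seeing the data. The count was 5 without the 10 min libraries, 15 with the replicate block, 17 with at least 20 counts on average and 56 with a pseudocount of 5, and it rose to 52 without the first wild-type and 56 without the first knockout library at 10 min.

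Of 10874 tested regions that HOMER lists as intergenic, on the plus strand, 1717 changed, 956 higher and 761 lower in the libraries labelled knockout. A region on chromosome 16 (hg38, 16394973 to 17100768, beyond NPIPA7) fell from 7434 ± 1069 to 36.1 ± 8.68 CPM (SD, n = 8; log2 fold change -7.69 ± 0.10 SE, adjusted p = 1.05e-36). The region next to LINC01036 (chromosome 1, 187361245 to 187442627) fell with that gene (-8.12 ± 0.31), and the region beyond SMIM3 (chromosome 5, 150797737 to 150845520) fell with SMIM3 (-7.28 ± 1.02). A region on chromosome 17 (16654851 to 16689240) had 242 counts in wild type and 2 in knockout, a ratio of 122 (95% interval 33.3 to 1009). Rises were found beyond SERPINI1 (chromosome 3, 167826570 to 167894947, 7.16 ± 0.50) and LINC01694 (chromosome 21, 45604057 to 45642724, 6.77 ± 1.01). Pooled counts gave smaller rises than these fitted sizes, 48.6-fold and 45.5-fold. Beyond LINC00839 (chromosome 10, 42496338 to 42512510) there were 464 counts against 3, a ratio of 154 (interval 52.4 to 750), and by ABCA9-AS1 (chromosome 17, 68956393 to 68973487) 316 against 3, a ratio of 105 (interval 35.6 to 511). GENCODE genes of the gene table lie inside 4 of these 8 regions: those on chromosome 16, beyond SERPINI1 (LRRC77P and MEMO1P3), beyond LINC01694 and on chromosome 17 from 16654851 (RNASEH1P2). With ERCC scaling the split was 1321 higher and 584 lower, and 1074 regions passed with replicates summed, chosen after seeing the data.

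Labelled RNA relative to the spike-ins rose over the labelling course in both genotypes, with a difference between genotypes that was not steady in time. The ratio of gene to ERCC counts was 0.220 ± 0.002, 0.893 ± 0.012, 0.568 ± 0.009 and 2.11 ± 0.01 in wild type at 10, 20, 30 and 60 min (SD, n = 2), and 0.259 ± 0.002, 0.707 ± 0.058, 1.15 ± 0.03 and 2.55 ± 0.02 in the libraries labelled knockout. The average difference in log2 ratio, knockout minus wild type, was 0.30 and did not pass (exact permutation p = 0.088). The ratio rose by 0.0458 per min in knockout and 0.0357 in wild type, a log2 difference of 0.36 (exact permutation p = 0.0741). Without the 20 min libraries, chosen after seeing the data, the average difference was 0.51 (exact permutation p = 0.00926, the smallest 216 arrangements can give). Only at 20 min was knockout lower (-0.34), and at each other time both knockout libraries lay above both of wild type. Leaving out 20 min thus fixed that p, which adds no support. The slope difference passed with slopes through the origin (0.32, exact permutation p = 0.0478) and when a library of 60 min was left out: 0.44 and 0.43 without the first or second wild-type library (exact permutation p = 0.0124 in both cases), and 0.35 and 0.37 without the first or second knockout library (exact permutation p = 0.0154 in both cases).

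Introns made up a smaller share of reads in the libraries labelled knockout at each time. Intron counts over intron plus gene-table counts were 40.4% ± 0.07, 43.4% ± 1.27, 42.6% ± 0.07 and 38.8% ± 0.01 in wild type at 10, 20, 30 and 60 min (SD, n = 2), and 39.1% ± 0.03, 41.6% ± 0.29, 40.9% ± 0.24 and 37.6% ± 0.13 in knockout. The average difference was -1.51 percentage points (exact permutation p = 0.00154, the smallest 1296 arrangements can give). From 10 to 60 min the share fell by 1.52 points (exact permutation p = 0.0286, the smallest 70 arrangements can give), with higher values at 20 and 30 min than at 10 min. That fall did not pass without either wild-type library at 10 min (-1.32 and -1.29) or either knockout library at 60 min (-1.28 and -1.35; exact permutation p = 0.0857 in each case). Intergenic reads took a larger share in knockout on average, by 0.26 points (exact permutation p = 0.00309). The difference was 0.65 points at 10 min (9.92% ± 0.06 against 10.6% ± 0.05) and 0.08, 0.18 and 0.11 at 20, 30 and 60 min, and at 20 min the libraries overlapped (10.88% and 10.94% in knockout, 10.92% and 10.75% in wild type). The permutations of both shares take the 2 libraries of a group as independent, which the labels do not state. With replicates averaged, chosen after seeing the data, neither the intron nor the intergenic difference passed. That test has too few arrangements to reach the threshold, so it does not decide. The contrast of long with short genes, in log2 CPM, differed by 0.88 at 10 min, -0.13 at 20 min, -0.50 at 30 min and -0.17 at 60 min, knockout minus wild type. These opposite values averaged 0.02 (exact permutation p = 0.937), which does not show that length played no part. That average turned to -0.06 without the first wild-type library at 10 min and to -0.004 without the first at 30 min, to -0.05 by exon length and to -0.22 with narrower length groups. Across the groups the contrast was largest at 10 min, where fewest genes were detected. It ran from 5.17 to 6.37 in the 10 min libraries, where 13904 to 15004 genes had at least 10 counts. Next came wild type at 30 min (4.31 and 4.52), with 15962 and 15498 such genes. Within the 10 min libraries the contrast did not follow detection. It was 6.36 and 6.37 in knockout (13904 and 15004 genes), against 5.17 and 5.80 in wild type (14367 and 14442 genes). What part detection had in the genotype difference was not tested and stays open.

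**Figure D2:**
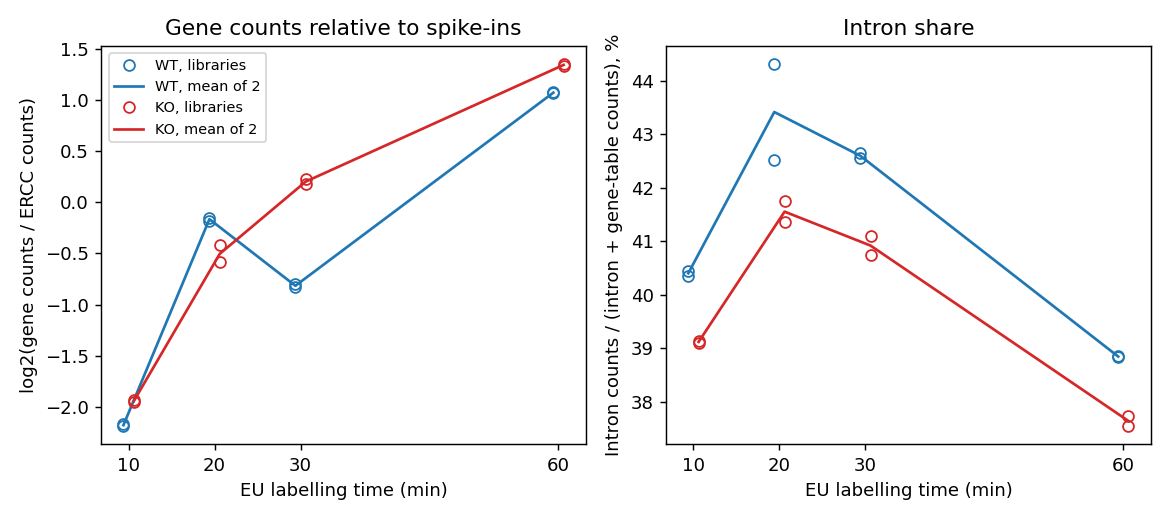
Left, log2 of gene counts over ERCC counts, and right, intron counts as a percent of intron plus gene-table counts, both against EU labelling time in min. Circles are libraries and lines join the means of 2 libraries per group: the knockout intron share lies below wild type at each time (37.6% against 38.8% at 60 min), and the spike-in ratio of wild type is lower at 30 min (-0.82) than at 20 min (-0.16).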

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

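The tests of chance capture, of spike-in amount and of labelled RNA entering the libraries were chosen only after the result was seen.

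The genotype difference depended on labelling time for 39 genes by the interaction test of edgeR. The leading ones were NTHL1 (adjusted p = 1.45e-07), MTATP6P1 (adjusted p = 2.86e-06), ADAMTS1 (adjusted p = 9.80e-06), SRRM2 (adjusted p = 0.00013) and MALAT1 (adjusted p = 0.000158). The MALAT1 difference was positive at 4 of 4 times and differed in size, from 0.25 to 0.87. Of 100 splits of the libraries within times, drawn from 648, 6 gave as many genes, the real split included, and the highest other split gave 983. The splits with most genes exchange genotypes at some whole times and turn the average genotype difference into an interaction, so these splits do not decide whether chance can be excluded here.

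The log2 ratio of gene to spike-in counts differed between genotypes in opposite directions. Knockout minus wild type was 0.24 at 10 min, -0.34 at 20 min, 1.02 at 30 min and 0.27 at 60 min, with both knockout libraries on 1 side of both wild-type libraries at each time. The contrast of long with short genes behaved likewise, at 0.88 at 10 min, -0.13 at 20 min, -0.50 at 30 min and -0.17 at 60 min. That contrast was largest at 10 min, where fewest genes were detected. Within the 10 min libraries it did not follow the number of genes detected, so what part detection had in it stays open. Differences between times were not tested for either measure. Groups of 2 libraries were too small to test for outlying libraries.

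The spike-in ratio did not rise steadily with labelling time, since wild type was higher at 20 min than at 30 min. Unequal addition of spike-in would change the ratio without changing the number of gene molecules. That number was estimated without spike-ins, as gene counts over the excess scatter between replicates, which takes all of that excess as PCR copies. The estimate was higher in wild type at 20 min than at 30 min by 0.829 on the log2 scale, against 0.65 for the ratio. Its SD of 0.095 is over 10 gene sets of the same libraries. Scatter was similar in the 2 groups (18.8 and 17.9), so the difference came mainly from gene counts (8474000 and 4516000 on average). Those counts also enter the ratio. The estimate thus argues against spike-in amount as the whole cause only if all the excess is PCR copies. Across the 8 groups the estimate rose with the ratio (Spearman rho 0.9524, exact permutation p = 0.00114, and Pearson r 0.983, exact permutation p = 0.000198). Without the 2 groups farthest from the median, r was 0.996. A difference in labelled RNA entering the libraries would give this. Both measures were also lowest at 10 min and highest at 60 min in each genotype, which the permutation ignores. The correlation therefore does not decide the cause. Within times the knockout minus wild-type estimates were -0.12, -0.33, 1.02 and -0.31, so the higher knockout ratios at 10 and 60 min were not mirrored, and RNA input, labelling and genotype stay open there.

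Many genes were close to all or none between the genotypes: 308 were lower and 272 higher in knockout by over 16-fold, and among all changed genes 52 had 0 counts in all 8 knockout libraries and 30 in all 8 wild-type libraries. Loss or gain of chromosome segments would move the neighbours too, but the median signed log2 change of the 6 nearest expressed genes was 0.1341 (quartiles -0.11 and 0.43, and -0.06 to 0.05 in 1000 shuffles) and 5 of the 580 genes had neighbours moving by over 2, which argues against segments as the main cause and leaves a small shared shift. If molecules were captured by chance in each group, exchanging the genotype labels at 2 of the 4 times would give about as many such genes at the same p, and the 3 exchanges gave 57, 67 and 78 genes against 580. The highest was 13.45%, above the 10% set before this value was computed for excluding chance capture, which therefore stays open for part of these genes, and the 91 of 97 that moved the same way in introns decide nothing, as intron and exon reads share libraries. Whether the differences follow from METTL3 loss or from descent from different cells also stays open, as the labels name no clones.

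Replicate libraries differed beyond counting noise, by 7.39 to 32.8 times. Variation between cultures in each gene's level would make this ratio grow with the count, whereas PCR copies of few molecules would leave it flat. Over the 8 groups the ratio in genes of 500 to 1000 counts was on average 1.04 times that in genes of 50 to 100 counts. This argues against culture variation as the main source and is consistent with PCR copies of few captured molecules. The p-values may then describe sampling of molecules more than variation between cultures, which stays untested.

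Other splits bear on the remaining counts. Among 100 splits that exchange single libraries within times, the real one was the largest for the genotype effect on genes (4041 against at most 1713). The same held for introns (1646 against 788), intergenic regions (1717 against 688) and the intron to exon ratio (31 against 2), each with 1 of 100 as large. These splits take the 2 libraries of a group as independent, which the labels do not state. Chance differences between whole groups are therefore not excluded. For the gene lists, 5 of 100 splits called at least the 6 lists, up to 7, so chance is not excluded for the number of lists. For labelling time, tested on the 8 libraries of 10 and 60 min without a genotype term, 2 of 35 splits gave at least the real 134 genes. They were the real split and that by genotype, with 487 genes. The genotype difference enters the spread of this fit, unlike that of the fit that called 1758 genes. These splits therefore do not decide whether chance can be excluded for labelling time.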

How the results depend on the processing

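Of 5714 values of named genes, lists and regions under the alternatives, 5343 kept direction and side of the threshold, 259 lost the call, 54 gained it and 58 changed sign; causes were not tested unless named. Alternatives without the 10 or 20 min libraries, with replicates summed or averaged, or limited to genes in both tables were chosen after seeing the data. Where a group kept 1 library, that library is assumed to vary like the other groups. Small changes are often missed: 17.9% of 1.5-fold genotype changes were recovered in simulated counts. The shallowest library, at 10 min, held 3221166 gene counts, and whether depth sets this limit was not tested.

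With ERCC scaling, which shifts all genes, 1368 genes passed at 20 min, 5659 at 30 min, 4109 for the interaction and 18058 for labelling time. Signs turned for HAT1 (0.22), TADA3 (0.046), METTL14 (0.16), BRPF3 (0.24), TRRAP (0.13), CREBBP (0.28), TADA2A (0.17), NCOA3 (0.18), RBBP7 (0.12), TAF1 (0.27), ZC3H13 (0.026), NSUN6 (0.083), NPM1 (0.015), NOP58 (0.0145), HSPD1 (0.041) and, over time, RNU4-1 (0.36). The fry test, which does not compare a list with other genes, called 22 lists, and 28 with ERCC scaling. There the direction turned for these lists, with adjusted p: m6A writers 0.00432, readers and erasers 2.97e-05, acetyltransferases 0.000655, deacetylases 0.000272, heterochromatin 0.000165, RNA polymerase II 0.000444, G1 and S phase 0.000523, G2 and M phase 7.58e-06, ribosomal proteins 0.000104, small nuclear RNA 0.434, small nucleolar RNA 0.0472, long noncoding RNA 6.98e-05, unfolded protein response 0.0485, heat shock 0.000976, cholesterol 0.108, glycolysis 0.00921 and extracellular matrix 0.0346.

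DESeq2 called 4131, 1525, 1497 and 948 genes at 10, 20, 30 and 60 min, 3162 for time and 809 for the interaction. Fits of a time alone gave 81 at 10 min and 2628 at 60 min, and of a genotype alone 437 (wild type) and 511 (knockout) for time, with fewer samples in each. A fit of a time alone also takes its spread from that time only, and replicate scatter was larger at 10 min than at 60 min. No filter gave 93 interaction genes, and the 1.2-fold test 2653 genotype genes. The intron to exon ratio gave 56 genes with a pseudocount of 5, 17 with at least 20 counts on average and 5 without 10 min. Summed replicates gave 2255 genes, 1096 intron genes and 1074 intergenic regions. The spike-in ratio difference was 0.51 without 20 min, the only time with a lower knockout ratio (exact permutation p = 0.00926). The slope difference through the origin was 0.32 (exact permutation p = 0.0478). With replicates averaged, the intron share difference of -1.51 and the intergenic one of 0.256 had an exact permutation p of 0.125, the smallest possible. Gene length turned to -0.048 by exon length and -0.22 with the narrower length groups (10% each). Without 10 min, KAT6B turned to -0.078, TADA2A to 0.055, and the ribosomal protein (adjusted p = 0.95) and long noncoding RNA (adjusted p = 0.88) lists changed sign, as did extracellular matrix with summed replicates (adjusted p = 0.787).

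Replicate numbers did not pair the libraries: over 28 pairs of groups the deviations correlated from -0.012 to 0.022. With the replicate block the counts were 4038 genes by genotype, 90 for the interaction and 15 for the ratio.

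Leaving out each library in turn gave 412 to 1343 genes at 20 min, 386 to 1206 at 30 min and 226 to 872 at 60 min, lowest without a library of that time and highest without a knockout library of 10 min. It gave 69 to 539 for the interaction, 1082 to 2559 for time and 21 to 56 for the ratio. The slope difference ran from 0.31 to 0.44, the time change in intron share from -1.74 to -1.28 and gene length from -0.057 to 0.10. Gene values ran from -0.16 to 0.040 (BRPF3), -0.038 to 0.15 (KAT6B), -0.07375 to 0.018 (CREBBP), -0.29 to 0.18 (KAT2A), -0.38 to 0.013 (NCOA3) and -0.10 to 0.0087 (TAF1). Adjusted p ran from 0.671 to 0.992 for ribosomal proteins, 0.791 to 0.998 for small nucleolar RNA, and 0.804 to 0.992 for the long noncoding RNA and extracellular matrix lists.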

Other observations

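The tests of gene lists over labelling time were chosen only after the data were seen, and so were the members named here. Ribosomal protein genes took a smaller share of the labelled RNA at 60 min than at 10 min: 72 of 83 fell and 0 rose, with a median log2 change of -0.94 (camera adjusted p = 3.40e-57, adjusted p = 3.90e-05 with an estimated correlation). RPS3 fell from 799 to 306 CPM (log2 change -1.38 ± 0.10 SE, n = 4 libraries per time, adjusted p = 3.10e-14), RPS6 by -1.09 ± 0.11 and RPL3 by -0.85 ± 0.09, each by similar amounts in wild type (-1.35, -1.11 and -0.91) and knockout (-1.41, -1.07 and -0.79). The translation factor gene EEF1A1 fell by -1.21 ± 0.08. HOX genes also took a smaller share at 60 min, with 10 of 35 lower and 0 higher (median -0.70, adjusted p = 0.00415 with an estimated correlation), HOXC9 by -1.39 ± 0.17 and HOXA3 by -0.95 ± 0.12. With ERCC scaling both lists rose, with medians of 2.37 and 2.60, against 3.48 for all genes, so they rose less than the median gene.

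ZNF genes moved the other way, with 101 of 455 higher at 60 min and 1 lower (median 0.66, adjusted p = 8.43e-05 with an estimated correlation), or 3.94 with ERCC scaling. Among nuclear and host long noncoding RNAs 11 of 25 took a smaller share and 4 a larger one (median -0.46, adjusted p = 0.00479 with an estimated correlation). The snoRNA host genes GAS5 (-0.92 ± 0.09) and SNHG1 (-0.88 ± 0.12) and MALAT1 (-0.55 ± 0.04) were lower, while NORAD (0.84 ± 0.13), TUG1 (0.94 ± 0.15) and KCNQ1OT1 (0.54 ± 0.08) were higher. In all, 18 of 31 lists were called over labelling time, 16 lower and 2 higher, and 14 with an estimated correlation, 13 lower and 1 higher. Camera compares a list with the other genes, and the median of all tested genes rose by 0.24. Lists that hardly moved were also called lower, such as ribosome biogenesis (median -0.02, 6 of 35 lower) and H3K9 methylation and heterochromatin (median -0.07, 4 of 25 lower). A list called lower is thus lower relative to other genes and need not have lost share. As 2 of 35 splits of the 8 libraries gave at least as many genes as the real split by time, the list calls carry the same limit as the count of genes.

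By gene type, 1534 of 13716 tested protein-coding genes were higher in the libraries labelled knockout and 1710 lower. Antisense genes had 99 of 1650 higher and 44 lower, and lincRNA genes 114 of 1459 higher and 113 lower. These counts were not tested against each other.

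The first principal component of log2 CPM held 17.3% of the variance and separated the genotypes, with the wild-type libraries from -84.5 to -51.0 and those labelled knockout from 50.1 to 113. The second, with 12.8%, set the 10 min libraries (79.2 to 121) apart from the later ones (-57.2 to -3.48).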
